A study of Mus musculus with 6 samples.

How the data were processed

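RNA was sequenced from the esophagus of mice that had taken the carcinogen 4-nitroquinoline 1-oxide (4-NQO) in their drinking water. Per the labels, the mice started at 8 weeks of age, drank 100 µg/ml for 16 weeks and then plain water for 12 weeks, a schedule that gives esophageal squamous tumors. From 2.5 weeks before sacrifice they were injected with 10 µg of antibody 2 times a week, either DTA-1, an agonist antibody against the T cell co-receptor GITR, or an isotype control antibody. The tissue was peeled and enriched for invading cells, minced and frozen, and polyA RNA was sequenced. Each group has 3 libraries, named here by group and replicate number. The labels do not say that each library is a separate mouse, so p-values measure the spread between these samples, which may be partly technical.

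Each deposited file holds whole-number read counts per Ensembl gene for 1 library, and the authors deposited them without normalization. Per the submitters' processing notes, cutadapt 1.13, STAR, HTSeq 0.6.1p1 and DESeq2 1.14.1 were used with mouse build mm10. The role, order and settings of these tools, including the strand setting of the counting, are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical gene copies such as immunoglobulin, hemoglobin, keratin and late cornified envelope genes, are therefore uncertain. The files list 54232 gene IDs each, of which 153 had no symbol in the reference table. All mitochondrially encoded genes are listed at 0 in every library. Gene positions come from GENCODE release M21 on GRCm38, the assembly named mm10.

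Total counts were 25216729, 23147873 and 29065162 in isotype libraries 1, 2 and 3, and 23802493, 23766069 and 23914043 in DTA-1 libraries 1, 2 and 3. A gene seen with 3 reads lies between 0.108 and 0.141 CPM (counts scaled to a common library size) at these depths, which is the floor used here and covers counting error only. No pair of libraries matched within sampling noise, the smallest median chi-square per gene being 3.91 against 0.455 for noise alone.

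Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 15763 genes. Counts were scaled by TMM and tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with treatment as the sole term and Benjamini-Hochberg adjustment at 0.05. Fold changes are DTA-1 over isotype on a log2 scale, and CPM values use TMM-scaled library sizes. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as alternatives. Before the data were examined, 31 gene lists with 547 symbols were fixed, covering cell types the tissue can hold, immune programs, epithelial states and library quality, and all 547 symbols were found. The 29 lists with at least 3 tested members, without the sex-linked genes, were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. List scores are means of log2 CPM over tested members, with a prior count of 2.

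Named genes followed a rule fixed at the same time. It took up to 8 genes in each direction past the threshold, with a mean log2 CPM of 0 or more, no overlap between groups and a symbol that is not a predicted model, or, with fewer than 5 past it, the 5 genes with the smallest p in each direction. It added the 3 members with the smallest p of the 8 called lists with the smallest p, and 12 genes given whatever their values: Tnfrsf18, Tnfsf18, Foxp3, Cd4, Cd8a, Gzmb, Ifng, Cd274, Il13, Ctla4, Krt5 and Mki67. Genes outside this rule were chosen after their values were seen. Some are members of the fixed lists, and others, such as late cornified envelope genes, belong to none of them. 1 gene that the rule selected is not reported here.

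The steps were tested on simulated data for the comparison of DTA-1 with isotype, drawn for 15763 genes with the estimated dispersions and 200 changed genes. The edgeR test recovered 6% of 100 genes changed 2-fold and 53% of 100 changed 4-fold, with 4 false calls among 63. DESeq2 recovered 29% and 76%, with 58 false calls among 163. With no gene changed, edgeR called 0 genes, DESeq2 24, and camera called 2 lists. Each gene was drawn independently, so the simulated counts lack the correlation between genes of the real libraries, whose median estimate within lists was 0.41. False calls of DESeq2 and camera in the real data can therefore be more numerous.

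Alternatives covered 3 other scalings, 2 other filters, removal of muscle genes, the replicate number as a block, a muscle score as covariate and each library left out in turn. Added after the data were seen were a squamous score as covariate, the newer edgeR method, a fit without isotype 3 and DTA-1 2, and the refits of DESeq2. Scaling by library totals alone shifted the median fold change of all genes from -0.03 to -0.19, and list values under it are to be read against that shift.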

Results

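RNA-seq counts were obtained from 6 esophagus libraries of mice with carcinogen-induced squamous disease, 3 from mice given the GITR agonist antibody DTA-1 and 3 from mice given an isotype antibody. The libraries held 23147873 to 29065162 counts. The design poses 1 comparison, DTA-1 against isotype, which asks how the diseased tissue differs after GITR agonism.

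On average, DTA-1 libraries carried more transcripts of striated muscle and mitochondrial respiration and fewer of squamous epithelium, NRF2 targets and the cell cycle. B cell and immunoglobulin transcripts were more abundant with DTA-1, while T cell transcripts were scarcer. These were shifts of whole gene lists, called by camera at a preset correlation, and no list passed with an estimated correlation or by fry. DTA-1 replicate 1 lay within the isotype range for the cell cycle, basal squamous and differentiated squamous scores. The groups overlapped for the T cell and B lineage scores. The striated muscle list took 16.7% ± 2.73 of counts in DTA-1 libraries and 10.3% ± 3.21 in isotype libraries (SD, n = 3 each). The basal and differentiated squamous lists together took 2.64% ± 2.0 against 6.23% ± 0.707.

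No single gene passed edgeR's test, whose smallest adjusted p was 0.39. At an unadjusted p under 0.05 edgeR counted 2006 genes, 12.7% of those tested, 821 of them higher and 1185 lower with DTA-1. Limma-voom called 0 genes and counted 2172 at the unadjusted level. DESeq2 called 177 of 16671 genes, 42 higher and 135 lower. On the 15763 genes tested by edgeR it called 201, 40 higher and 161 lower, where counts simulated for those genes with none changed gave it 24. The simulated genes were drawn independently, while genes in the real libraries moved together, so 24 is not a full null for the 201. Other splits of the 6 libraries into 3 and 3 gave DESeq2 up to 223 calls, against 177 in the real split. Without DTA-1 replicate 1, edgeR called 601 genes, 62 higher and 539 lower, among them Ighg2c and Scn4b (higher) and Nlrp10, Sdr42e1, Fam107b, Slc37a2, Cdh1, Gclc, G6pdx and Mki67 (lower). DESeq2's count went to 56 without isotype replicate 2, 901 without isotype replicate 3, 2444 without DTA-1 replicate 1, 41 without DTA-1 replicate 2 and 42 without DTA-1 replicate 3.

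The 5 genes with the smallest p on the lower side were Calml3, Nlrp10, Slc37a2, Sdr42e1 and Fam107b. Calml3, which encodes a calmodulin-like protein of squamous epithelium (chromosome 13, 3802896 to 3804316, GRCm38, ENSMUSG00000063130), averaged 296.4 ± 43.0 CPM in isotype and 78.5 ± 28.0 in DTA-1 libraries (SD, n = 3 each). Nlrp10, an NLR family gene on chromosome 7 (108921852 to 108930178, ENSMUSG00000049709), averaged 11.8 ± 1.69 against 3.34 ± 0.703 CPM. Slc37a2, a sugar-phosphate transporter gene on chromosome 9 (37227585 to 37255738, ENSMUSG00000032122), averaged 22.3 ± 7.40 against 5.96 ± 1.05 CPM. Sdr42e1 on chromosome 8 (117661399 to 117673689, ENSMUSG00000034308) averaged 41.4 ± 9.14 against 14.4 ± 3.59 CPM, and Fam107b on chromosome 2 (3570488 to 3782142, ENSMUSG00000026655) averaged 37.6 ± 4.20 against 18.1 ± 2.30 CPM. In all 5 genes each DTA-1 library lay below each isotype library, which the choice by smallest p favors. The log2 fold changes were -1.92 ± 0.29 (SE) for Calml3, -1.82 ± 0.27 for Nlrp10, -1.90 ± 0.31 for Slc37a2, -1.52 ± 0.25 for Sdr42e1 and -1.06 ± 0.17 for Fam107b. All 5 had an adjusted p of 0.39 in edgeR and did not pass. By DESeq2 all 5 fell, with adjusted p of 2.04e-05 for Calml3, 2.39e-06 for Nlrp10, 0.000213 for Slc37a2, 0.00051 for Sdr42e1 and 0.00237 for Fam107b. DESeq2 kept these calls without any single library, except Fam107b, whose adjusted p was 0.057 without isotype replicate 2. With the muscle score as covariate DESeq2 kept Calml3 alone of the 5 (adjusted p = 0.0022), and with the squamous score Calml3 (0.00195) and Nlrp10 (0.0471). The squamous fit cannot decide on the epithelial share for these genes. The choice by p favored genes low in DTA-1 replicate 1, whose squamous score (8.15) lay within the isotype range of 8.1 to 8.43. Without both isotype replicate 3 and DTA-1 replicate 2, DESeq2 lost Slc37a2 (adjusted p = 0.0656) and Fam107b (0.0733). With the replicate number as a block it kept all 5, the adjusted p being 0.0258 or less.

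The genes reported on the higher side were the immunoglobulin gene Ighg2c, the muscle receptor gene Chrna1, Scn4b and Unc119. Ighg2c, an immunoglobulin heavy chain constant gene (chromosome 12, 113285325 to 113288932, ENSMUSG00000076612), averaged 9.11 ± 6.09 CPM in DTA-1 and 0.651 ± 0.214 in isotype libraries (SD, n = 3 each), and reads shared with related constant genes make its level uncertain. Chrna1, the muscle acetylcholine receptor alpha subunit (chromosome 2, 73563215 to 73580338, ENSMUSG00000027107), averaged 86.7 ± 12.2 against 42.3 ± 8.18 CPM. Scn4b, a sodium channel beta subunit (chromosome 9, 45138395 to 45154152, ENSMUSG00000046480), averaged 105 ± 21.7 against 55.5 ± 4.68 CPM, and Unc119 (chromosome 11, 78343482 to 78349164, ENSMUSG00000002058) averaged 47.1 ± 8.28 against 23.6 ± 4.31 CPM. Every DTA-1 library lay above every isotype library for these 4 genes, which the choice by smallest p favors. Other immunoglobulin constant genes looked at (Ighg1, Ighg2b, Ighg3, Igha, Ighm and Igkc) overlapped between the groups. Ighg1 stood at 26.9 CPM in isotype replicate 2 and 0 in DTA-1 replicate 1, and Igkc at 118 and 22.1 CPM. The log2 fold changes were 3.80 ± 0.61 (SE), 1.03 ± 0.20, 0.92 ± 0.19 and 0.997 ± 0.20 for Ighg2c, Chrna1, Scn4b and Unc119. None of the 4 passed edgeR, each at an adjusted p of 0.39. By DESeq2 all 4 rose, with adjusted p of 4.46e-07 for Ighg2c, 0.0112 for Chrna1 and 0.0239 for both Scn4b and Unc119. Among DESeq2's refits without single libraries, Ighg2c kept its call in each. DESeq2's adjusted p for Chrna1 was 0.15 without isotype replicate 2 and 0.222 without DTA-1 replicate 2. For Scn4b it was 0.102, 0.178, 0.213 and 0.0851, and for Unc119 0.102, 0.283, 0.299 and 0.0775, in DESeq2's refits without isotype replicate 1, isotype replicate 2, DTA-1 replicate 2 and DTA-1 replicate 3. With the muscle or the squamous score as covariate DESeq2 kept none of the 4, the adjusted p lying between 0.292 and 1. Without both isotype replicate 3 and DTA-1 replicate 2, DESeq2 kept Ighg2c alone of the 4 (adjusted p = 0.000288). With the replicate number as a block DESeq2 gave Ighg2c no adjusted p and lost Unc119 (0.0582), and it kept Chrna1 (0.0458) and Scn4b (0.0394).

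**Figure D1:**
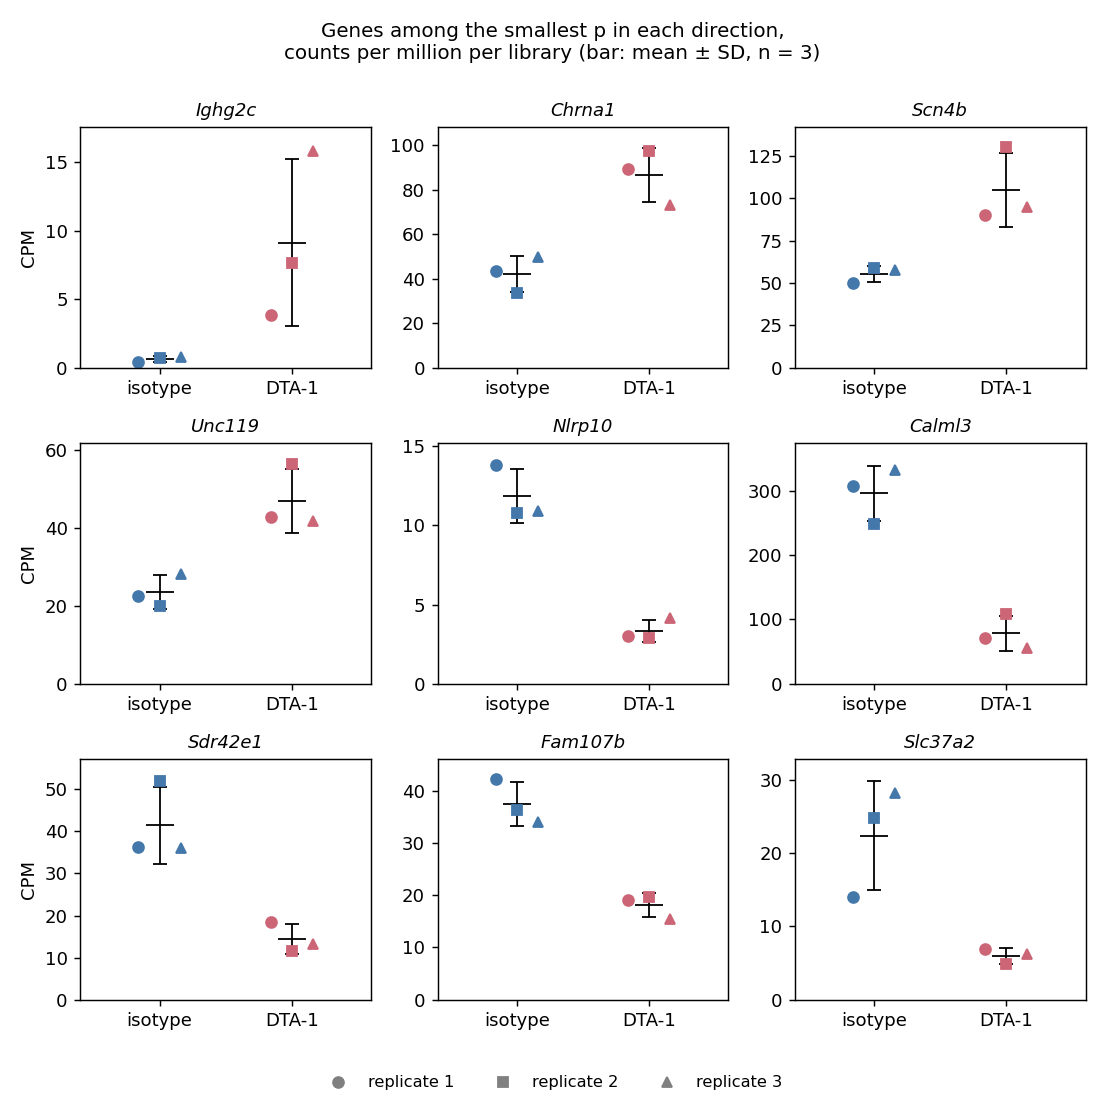
CPM per library (y axis, from 0) of 5 genes on the lower and 4 on the higher side among those with the smallest p, for isotype and DTA-1 libraries (x axis). Points are libraries with the marker giving the replicate, and bars give the mean ± SD of 3; in all 9 genes the groups do not overlap, Calml3 averaging 296.4 CPM in isotype and 78.5 in DTA-1 libraries.

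Epithelial transcripts were scarcer on average with DTA-1, by list score in replicates 2 and 3 alone. In DTA-1 replicate 1 the differentiated score was 8.31, within the isotype range of 8.29 to 8.59 (mean log2 CPM). Its basal score was 7.87, within the isotype range of 7.26 to 8.66. Of 29 differentiated squamous genes, which build the cornified upper layers, 27 had negative fold changes, with a median of -0.96 (log2). Of 17 basal squamous genes all 17 did, with a median of -0.87. The squamous lists took 4.92%, 1.21% and 1.78% of counts in DTA-1 replicates 1, 2 and 3, against 6.05%, 7.01% and 5.63% in isotype replicates 1, 2 and 3. The cornified envelope genes Cnfn, Sprr3 and Rptn averaged 314.4 ± 125, 477.9 ± 215 and 288.3 ± 118 CPM in DTA-1 libraries, against 692.1 ± 70.7, 1302 ± 426 and 849 ± 377 in isotype libraries (SD, n = 3 each). In each of these 3 genes, picked for the smallest p in the list, every DTA-1 library lay below every isotype library. Of all 29 differentiated genes 7 did so. The stem and progenitor factor Sox2 averaged 23.8 ± 9.44 against 51.7 ± 13.2 CPM, and the adhesion genes Cdh1 and Epcam averaged 134 ± 81.3 and 16.9 ± 10.0 CPM against 302.6 ± 83.2 and 42.9 ± 30.6. The basal keratin gene Krt5 averaged 1789 ± 1120 against 3177 ± 1660 CPM, with an adjusted p of 0.513 in edgeR. By camera with a preset correlation the differentiated list fell (adjusted p = 9.89e-10), as did the basal list (adjusted p = 0.000142). Both calls were lost with an estimated correlation, where the adjusted p was 0.648 for each. Without DTA-1 replicate 1 the medians were -1.70 for the differentiated and -1.41 for the basal list, and the basal median was -0.50 without isotype replicate 1. With the muscle score as covariate, the basal median turned to 0.91.

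NRF2 targets, genes of the oxidative stress response, and cell cycle genes went the same way as the epithelial lists. Of 16 NRF2 targets 13 had negative fold changes (median -0.69), and the list score was 7.23 ± 0.03 in isotype and 6.55 ± 0.40 in DTA-1 libraries (log2 CPM, SD, n = 3 each). Pgd and G6pdx, enzymes of the pentose phosphate pathway, averaged 142.7 ± 51.9 and 71.7 ± 34.6 CPM with DTA-1 against 268.2 ± 21.8 and 139.9 ± 5.62 with isotype. Gclc, of glutathione synthesis, averaged 48.5 ± 24.6 against 100.4 ± 11 CPM. All 25 cell cycle genes had negative fold changes, with a median of -0.67. The proliferation marker Mki67 stood at 62.6, 57.7 and 44.5 CPM in isotype replicates 1, 2 and 3, and at 61.9, 18.3 and 11.8 CPM in DTA-1 replicates 1, 2 and 3. Mcm7 and Tyms, genes of DNA replication, averaged 16.8 ± 5.34 and 4.03 ± 1.89 CPM against 23.5 ± 6.28 and 7.01 ± 3.92. Their adjusted p in edgeR was 0.475 for Mcm7, 0.495 for Tyms and 0.518 for Mki67. By camera with a preset correlation the NRF2 list fell (adjusted p = 0.000163) and so did the cell cycle list (adjusted p = 0.000285). With an estimated correlation both lists had an adjusted p of 0.648. The cell cycle median was -1.58 without DTA-1 replicate 1, -0.40 without DTA-1 replicate 2, -0.34 without DTA-1 replicate 3 and -0.38 without isotype replicate 1, and the NRF2 median was -1.09 without DTA-1 replicate 1. The cell cycle median turned to 0.52 with the muscle score and to 0.38 with the squamous score as covariate. The NRF2 median was -0.10 with the muscle score, where camera lost the call.

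Striated muscle transcripts took a larger share of counts in each DTA-1 library than in any isotype library, though most single genes overlapped. Of 29 striated muscle genes, 27 had positive fold changes (median 0.86), and the list took 14.76%, 19.81% and 15.47% of counts in DTA-1 replicates 1, 2 and 3, against 9.56%, 7.49% and 13.79% in isotype replicates 1, 2 and 3. Casq1, which stores calcium in the sarcoplasmic reticulum, averaged 1199 ± 356 CPM with DTA-1 and 622.8 ± 180 with isotype (SD, n = 3 each). The giant sarcomere gene Ttn averaged 5390 ± 1580 against 2778 ± 725 CPM, and the oxygen-binding Mb 4351 ± 808 against 2315 ± 771 CPM. Of the 29 striated muscle genes, 8 had every DTA-1 library above every isotype library, and Ttn was not among them. All 22 oxidative phosphorylation and citric acid cycle genes had positive fold changes, with a median of 0.49. Ndufs1 and Ndufb8, subunits of respiratory complex I, averaged 304.2 ± 51.4 and 236.5 ± 47.7 CPM against 205.7 ± 19.1 and 160.1 ± 10.4, and Idh3a averaged 371.9 ± 65.1 against 248.9 ± 31.3. By camera with a preset correlation both lists rose, the striated muscle list at an adjusted p of 1.99e-11 and the oxidative phosphorylation list at 1.17e-08. Neither call held with an estimated correlation, with an adjusted p of 0.648 for both. Both lists kept their calls in camera without any single library. With the muscle score as covariate camera lost the oxidative phosphorylation call, and the median of that list was 0.16. Smooth muscle genes, with a median of 0.11 and of -0.03 with library totals alone, did not pass (adjusted p = 0.132 by camera). Camera called them higher without isotype replicate 2 (0.0133), isotype replicate 3 (0.0238) or DTA-1 replicate 2 (0.00216), and their median ranged from -0.93 without DTA-1 replicate 3 to 0.52 without isotype replicate 2.

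**Figure D2:**
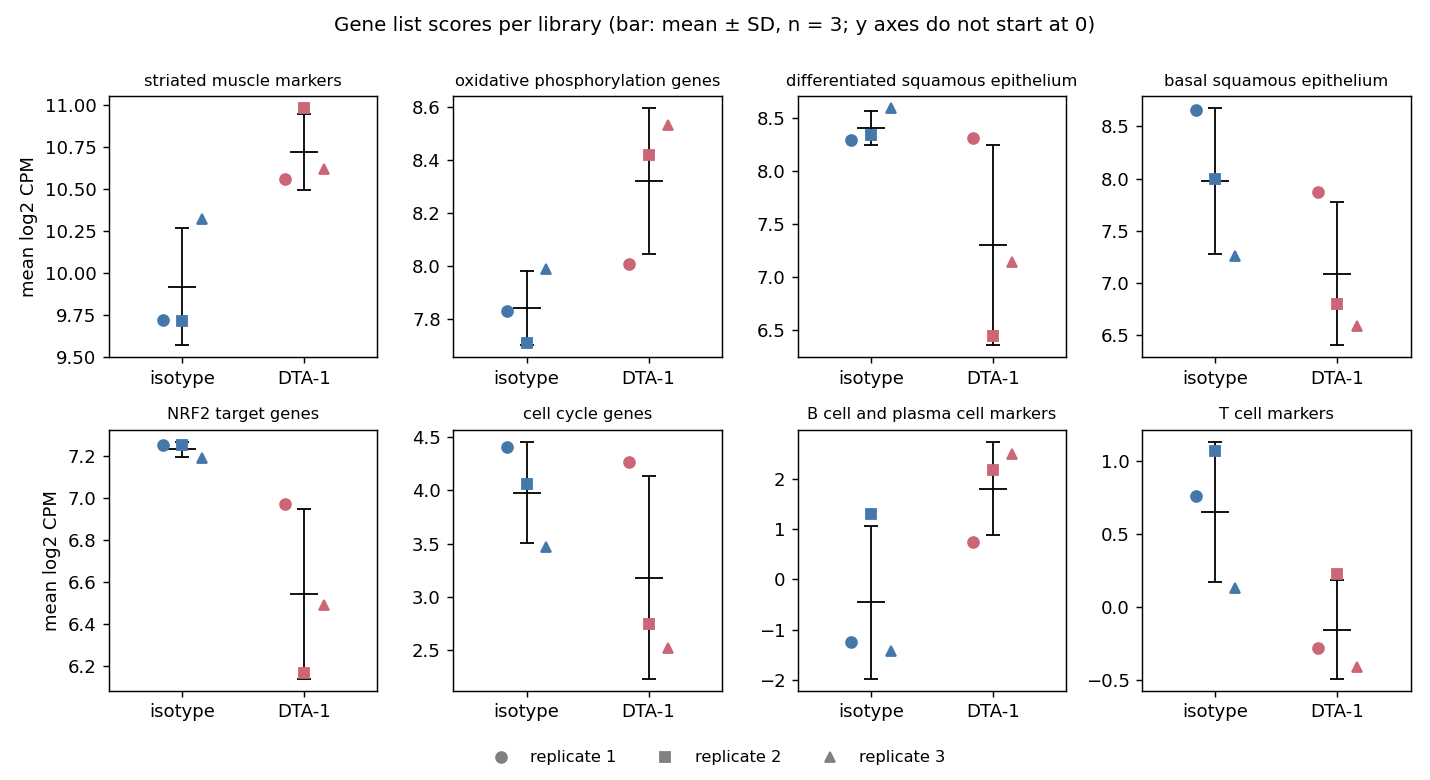
Mean log2 CPM over the tested members of 8 gene lists (y axes, not starting at 0) in isotype and DTA-1 libraries (x axis). Points are libraries with the marker giving the replicate, and bars give the mean ± SD of 3; DTA-1 replicate 1 lies within the isotype range for the cell cycle list (4.27 against 3.47 to 4.41) but above it for the striated muscle list (10.56 against 9.71 to 10.32).

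B lineage transcripts were more abundant with DTA-1 from a very low base. Of 13 tested B cell and plasma cell markers 12 had positive fold changes, with a median of 2.17 (log2). Pax5, a B cell transcription factor, averaged 0.595 ± 0.0983 CPM with DTA-1 and 0.124 ± 0.0959 with isotype (SD, n = 3 each). Ms4a1, which encodes CD20, averaged 1.43 ± 0.384 against 0.213 ± 0.308 CPM. Levels in isotype replicate 2 were closer to the DTA-1 libraries: the list score was 1.30 there, -1.25 and -1.42 in isotype replicates 1 and 3, and 0.75, 2.18 and 2.49 in DTA-1 replicates 1, 2 and 3. Ighm, the IgM heavy chain, stood at 187 CPM in isotype replicate 2 and at 33.5, 359 and 369 CPM in DTA-1 replicates 1, 2 and 3, against 4.79 and 9.41 CPM in isotype replicates 1 and 3. The list rose by camera with a preset correlation (adjusted p = 1.06e-08), and the adjusted p was 0.648 with an estimated correlation. Camera kept the call without any single library, the median being 4.46 without isotype replicate 2. The libraries with high B lineage scores also carried other tissue: isotype replicate 2 and DTA-1 replicate 3 had the highest adipocyte scores (5.89 and 6.97, against 3.10 to 5.11 elsewhere) and DTA-1 replicate 2 the highest red cell score (8.5, against 3.5 to 4.3).

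T cell transcripts were scarce in every library and scarcer with DTA-1. All 13 tested T cell markers had negative fold changes (median -0.75), as did all 10 tested regulatory T cell genes (median -0.70). The T cell surface and signaling genes Cd6, Cd3e and Lat averaged 0.284 ± 0.0831, 0.416 ± 0.198 and 0.793 ± 0.355 CPM with DTA-1, against 0.901 ± 0.280, 1.09 ± 0.355 and 1.63 ± 0.315 with isotype (SD, n = 3 each). Tnfrsf18, which encodes GITR, averaged 1.12 ± 0.528 against 1.94 ± 1.15 CPM, with a log2 fold change of -0.79 ± 0.65 (SE) and an adjusted p of 0.576 in edgeR. That fold change was -0.40 without isotype replicate 1, -0.44 without DTA-1 replicate 3 and -1.18 without isotype replicate 3, and lay between -0.61 and -1.02 without each of the other 3 libraries. The helper T cell gene Cd4 averaged 0.821 ± 0.785 against 1.55 ± 0.811 CPM, and the checkpoint genes Ctla4 and Cd274 averaged 0.621 ± 0.0277 and 9.34 ± 2.92 against 0.950 ± 0.336 and 10.9 ± 2.54. Their adjusted p in edgeR was 0.631 for Cd4, 0.503 for Ctla4 and 0.764 for Cd274. By camera with a preset correlation both the T cell list (adjusted p = 0.00225) and the regulatory T cell list (adjusted p = 0.0142) fell, and with an estimated correlation both had an adjusted p of 0.648. The T cell call was lost without DTA-1 replicate 1 (camera adjusted p = 0.054), and the regulatory T cell call without DTA-1 replicate 1 (0.143) or isotype replicate 1 (0.0573). The T cell median was -1.22 without DTA-1 replicate 2, and the regulatory T cell median -1.08 without isotype replicate 3.

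Foxp3, Cd8a, Gzmb, Ifng, Il13 and Tnfsf18 lay below the filter used for edgeR and limma-voom, and DESeq2 gave an adjusted p for Gzmb alone (0.431). Foxp3, the regulatory T cell factor, had 7, 6 and 5 reads in isotype replicates 1, 2 and 3 and 3, 3 and 2 in DTA-1 replicates 1, 2 and 3. Cd8a had 4, 14 and 8 reads in the isotype libraries and 0, 4 and 0 in the DTA-1 libraries, and Gzmb had 12, 21 and 3 against 2, 3 and 4. Tnfsf18, the GITR ligand gene, had 18, 1 and 2 reads against 2, 4 and 1. Ifng had 0, 4 and 0 reads against 2, 1 and 0, and Il13 had 0, 1 and 1 against 0 in each DTA-1 library. A difference in Ifng or Il13 was not detectable at this depth.

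Inflammatory lists were lower with DTA-1 on balance, but each hung on single libraries. Of 30 interferon gamma response genes 23 had negative fold changes (median -0.41), of 17 IL-17 and neutrophil-recruiting genes 16 did (median -1.06), and of 12 neutrophil markers 11 did (median -1.16). By camera with a preset correlation these 3 lists fell, with adjusted p of 0.0142, 0.00444 and 0.015 in that order. With an estimated correlation the adjusted p was 0.696 for the interferon gamma list and 0.648 for the IL-17 and neutrophil lists. Camera's adjusted p for the interferon gamma list was 0.907 without isotype replicate 2 and 0.537 without DTA-1 replicate 1. For the IL-17 list it was 0.176 without isotype replicate 1 and 0.0575 without DTA-1 replicate 3, and for the neutrophil list 0.438 and 0.149. The median of the neutrophil list was 0.11 without isotype replicate 1. That of the IL-17 list was -0.45 without isotype replicate 1 and -1.67 without DTA-1 replicate 1, and that of the interferon gamma list -0.14 without isotype replicate 2 and -0.62 without isotype replicate 3. With the muscle score as covariate, the interferon gamma and IL-17 medians turned to 0.27 and 1.135. With the squamous score camera lost the IL-17 and neutrophil calls, the medians being -0.20 and -1.37. The neutrophil marker Ly6g stood at 0.151 CPM or less in every library. S100a8, of the same list, averaged 688 ± 467 CPM with DTA-1 against 1530 ± 260 with isotype (SD, n = 3 each). Whether neutrophils or epithelial cells set these lists was not tested.

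Markers of other tissues differed between libraries within the groups. Endothelial genes rose by camera with a preset correlation (13 of 15 positive, median 0.33, adjusted p = 0.0048), with an adjusted p of 0.648 with an estimated correlation and a median of 0.21 without DTA-1 replicate 3. Adipocyte markers (12 of 12 positive, median 1.02) and red blood cell genes (5 of 5, median 3.15) also rose by camera, at adjusted p of 0.00414 and 0.0142, and both stood at an adjusted p of 0.648 with an estimated correlation. The red cell gene Hbb-bs stood at 1790 CPM in DTA-1 replicate 2 and at 50 to 108 CPM in the other 5 libraries, and its close copies share reads. Without DTA-1 replicate 2 the red cell median was -0.08 (camera adjusted p = 0.965), and the call was also lost without isotype replicate 1 (0.0573) or isotype replicate 3 (0.0857). The fat hormone gene Adipoq stood at 92.7 CPM in DTA-1 replicate 3, and without that library the adipocyte median was -0.10 (camera adjusted p = 0.231). Without isotype replicate 1 camera's adjusted p for that list was 0.18 and its median 0.67, and the median was 1.91 without isotype replicate 2. The stomach genes Gkn1 and Atp4a stood at 457 and 173 CPM in isotype replicate 3 and at 1.88 CPM or less in the other 5 libraries. The smooth muscle gene Myh11 ranged from 112 to 2890 CPM among isotype libraries and from 143 to 2520 CPM among DTA-1 libraries.

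With the muscle score as covariate camera still called 3 of its 15 lists in the same direction, the B lineage (median 4.85), differentiated squamous (-0.43) and adipocyte (2.34) lists. It called 3 in the opposite direction, now higher: the IL-17 (adjusted p = 0.0104), basal squamous (0.00213) and cell cycle (0.00169) lists. With the squamous score it still called 7 in the same direction, with medians that shrank to 0.11 for the B lineage, -0.24 for NRF2 targets, 0.17 for oxidative phosphorylation and 0.44 for striated muscle, and stood at -0.85 for the T cell, -0.65 for the regulatory T cell and -0.69 for the interferon gamma list. It called the cell cycle list in the opposite direction, now higher (2.54e-05). The neutrophil call was also lost on limma-voom values (camera adjusted p = 0.0769) and with library totals alone (0.0647), the red cell call on limma-voom values (0.104) and without both isotype replicate 3 and DTA-1 replicate 2 (0.577), and the regulatory T cell call under a stricter filter (0.3), where the T cell list could not be tested for want of members.

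The other lists did not pass camera. Type 2 cytokine genes and dendritic cell markers each had an adjusted p of 0.0568, invasion genes 0.084, Schwann cell and neuron markers 0.106 and the gastric, thyroid and airway list 0.126. Macrophage markers stood at 0.204, GITR and other co-receptors at 0.205, immediate-early and heat-shock genes also at 0.205 and fibroblast genes at 0.28. Hypoxia genes stood at 0.498, p53 targets at 0.585, type I interferon genes at 0.631 and mast cell, basophil and eosinophil markers at 0.871 in camera. The CD8 T and NK cytotoxic list had 2 tested members and the sex-linked list was left out of camera. Of the 14 lists that did not pass, smooth muscle included, camera called 10 without at least 1 single library: 7 without isotype replicate 3, 5 each without DTA-1 replicate 2 and DTA-1 replicate 3, 4 without isotype replicate 2 and 1 each without isotype replicate 1 and DTA-1 replicate 1. On the lower side, adjusted over the list alone, edgeR called 1 dendritic cell marker (Ccl22), 1 neutrophil marker (Cxcr2) and 3 gastric genes (Gkn1, Gkn2 and Pgc). The gastric calls rest on isotype replicate 3, without which the list median went from -7.16 to -0.72 (camera adjusted p = 0.361). Fry called 0 of the 29 lists, the smallest adjusted p being 0.309 for a shift in 1 direction and 0.197 for change in either direction.

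Across the 15763 tested genes, libraries correlated at 0.934 to 0.965 within isotype, 0.949 to 0.958 within DTA-1 and 0.916 to 0.972 between groups (Pearson r across genes of log2 CPM, genes not being independent replicates). The highest value, 0.972, joined DTA-1 replicate 1 and isotype replicate 3. The first principal component held 38.1% of the variance, with DTA-1 replicates 2 and 3 at 58.9 and 54.4 and DTA-1 replicate 1 at -13.9, between the isotype libraries at -54.6, -34.1 and -10.7.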

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

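The DESeq2 refits, the squamous covariate and the fit without both isotype 3 and DTA-1 2 were chosen after the data were seen. The count of 0 genes in edgeR held under every scaling, filter, covariate and block tried, with exceptions in the test and in 1 library: DESeq2 called 177 (42 higher, 135 lower), and leaving out single libraries gave 0 to 601 (0 to 62 higher, 0 to 539 lower). DESeq2's own count ranged from 41 to 2444 without single libraries, 2 to 840 higher and 33 to 1604 lower. With the squamous score as covariate DESeq2 called 24 genes, 14 higher and 10 lower. Without both isotype 3 and DTA-1 2 it called 76, 27 higher and 49 lower. With the muscle score it called 132, 21 higher and 111 lower, 1 of them among the 177. For each the cause was not tested, beyond fewer samples or residual degrees of freedom.

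Camera's 15 lists became 24 without both isotype 3 and DTA-1 2, 0 with an estimated correlation and 0 with fry; the estimated correlations were 0.094 to 0.991, far above the preset 0.01. The difference between mean within-group and between-group correlation was 0.008 over all genes and -0.0304 over the 500 most variable genes.

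Medians of called lists that changed sign did so under a covariate or without a library. Apart from lists adjusted for their own score, the cause was not tested. The muscle score gave 0.27 for interferon gamma response, 1.135 for IL-17, 0.91 for basal squamous, -0.12 for striated muscle, 0.52 for cell cycle and -2.30 for red cell genes. The squamous score gave 0.013 for basal squamous, 0.38 for cell cycle and -0.78 for red cell genes. The muscle score is the mean of the striated muscle list, and the squamous score that of the basal and differentiated squamous lists. Medians of these lists under their own score shrank by construction and carry no information. The red cell median was -0.26 without both isotype 3 and DTA-1 2. Medians without single libraries ranged from -1.59 to 0.11 for neutrophil, -0.10 to 1.91 for adipocyte and -0.077 to 3.69 for red cell genes. Among named genes, the muscle score gave 0.39 for Mcm7, 0.75 for Tyms, 0.21 for Mki67, 0.82 for Tnfrsf18, 0.10 for Cd274 and 1.02 for Krt5. The squamous score gave 0.085 for Mcm7, 0.031 for Tyms, 0.19 for Mki67 and 0.23 for Krt5. Cd274 ranged from -0.40 to 0.019 without single libraries. The muscle and squamous scores are confounded with treatment in 6 libraries, so these fits compare few residual values.

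Deviations from the group means correlated at 0.02, -0.33 and -0.09 in the same-numbered pairs, and isotype 2 correlated best with DTA-1 3 (0.36). So few libraries cannot show whether same-numbered replicates shared a litter or day, which the labels do not say. With the replicate number as a block edgeR called 0 genes, camera 17 lists and DESeq2 250 genes, 219 of them lower and 31 higher. Depth limits Foxp3, Cd8a, Gzmb, Ifng, Il13 and Tnfsf18, which had at most 21 reads per library. Of the remaining values, 679 gene values kept their direction and side, 494 list medians moved by less than the replicate spread and 43 by more, 16 and 14 of these with a change of sign in lists that were not called, and 20 gene values passed the threshold under an alternative.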

Other observations

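Of the tests in this part, the splits of the 6 libraries into 3 and 3 and the look at DTA-1 replicate 1 for genes called without it were set before their results were seen; the other tests, the gene families and the list overlaps were chosen afterwards.

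Late cornified envelope genes, which are expressed as keratinocytes finish differentiating, were among the genes that DESeq2 called lower. Of 21 such genes with an adjusted p, DESeq2 called 6 lower and 0 higher (two-sided Fisher's exact p = 1.24e-08, chosen after the calls were seen), with a median log2 fold change of -1.82. Lce3f averaged 35.8 CPM with DTA-1 and 117 with isotype, and Lce3a 45.0 against 130 CPM, near-identical copies making the split between members uncertain. The squamous lists fixed beforehand held 1 of the lower calls among 46 genes, Lor (Fisher's exact p = 0.312), and the striated muscle list 0 of the higher calls among 28 (p = 1). Among immunoglobulin variable segments DESeq2 called 7 of 31 higher and 0 lower (Fisher's exact p = 9.57e-13). The envelope and immunoglobulin families were picked from the calls they were tested on, and near-identical copies are not independent. A small p was thus built into the choice of each family, and neither p-value gives support of its own. Immune genes among DESeq2's calls went both ways. Those named here, and the hypoxia gene Car9, were picked after the calls were seen and are not all of the calls. Il1r2 (adjusted p = 0.00108) and Il18 (0.0112) were called lower, and Cd5l (0.031) and Nlrc3 (0.0259) higher. Also lower were Cxcr2, a neutrophil chemokine receptor (adjusted p = 0.00588), Havcr2, which encodes the checkpoint TIM-3 (0.0398), Ccl22, a chemokine that draws regulatory T cells (0.0436), and Car9, a hypoxia-induced carbonic anhydrase (0.00471).

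Without DTA-1 replicate 1, the 539 genes that edgeR called lower held 11 of 29 differentiated squamous genes (Fisher's exact adjusted p = 2.91e-08), 9 of 25 cell cycle genes (8.71e-07) and 5 of 16 NRF2 targets (0.00129). They held 2 of 17 basal squamous genes (Fisher's exact adjusted p = 0.474) and 0 of 13 B lineage markers. Fisher's test counts genes as independent. Over all 6 libraries the estimated correlations were 0.55 in the differentiated squamous, 0.814 in the cell cycle and 0.176 in the NRF2 list. These p-values therefore do not measure a treatment effect, and camera with an estimated correlation gave each of these lists an adjusted p of 0.648. The 62 higher genes held 0 of 29 striated muscle genes. Of the 539, 61 were also among DESeq2's 135 lower calls on all 6 libraries.

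The first pattern is the number of calls. There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. DESeq2 called 177 genes in the real split and up to 223 in the others, 4 of the 10 splits giving as many; camera called 15 lists against up to 20, again 4 of 10; and edgeR called 0 in all 10, its count at an unadjusted p under 0.05 being 2006 in the real split and up to 2145 in the others. DESeq2's 135 lower genes had a median log2 fold change of -1.50 (median SE 0.36) and of -1.01 (median SE 0.47) with the squamous score as covariate, 2 keeping their call as the fold shrank and the error grew; a smaller epithelial share cannot be told apart here, since 131 of 133 of these genes were picked with DTA-1 replicate 1 below each isotype library while its squamous score lay within their range.

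The second pattern is the loss of epithelial transcripts, seen in the list scores of DTA-1 replicates 2 and 3 but not of DTA-1 replicate 1. Crowding by muscle reads is argued against as the whole cause, since it would lower all other genes alike. On library totals alone, the middle gene of each library differed between group means by -0.169 (SE 0.089, log2). The fitted median fold change of all genes was -0.19, against fitted medians of -1.11 for the differentiated and -1.02 for the basal squamous list. With TMM scaling and the muscle score as covariate the differentiated and basal medians were -0.43 and 0.91. That score, however, is confounded with treatment and also tracks the makeup of the tissue. A smaller share of squamous epithelium in those 2 tissue pieces cannot be told apart for the 539 genes. In DTA-1 replicate 1 they lay at a median of -0.24 from the isotype mean, against -1.58 in the other two, but edgeR called 0 genes with that library and 601 without it, so the choice of genes already placed it apart from the other two. A wrong label on DTA-1 replicate 1 cannot be told apart either. There 69% of striated muscle genes lay nearer to DTA-1 replicates 2 and 3 than to isotype, short of the 75% set to exclude it. In the other fixed lists looked at, that share was 46.2% for B lineage, 13% for squamous, 9.1% for oxidative phosphorylation and 0% for cell cycle genes. Whether the antibody, tumor load or dissection set the epithelial share was not tested.

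The third pattern is the excess of B lineage transcripts. Lymph node carried over with the tissue would raise the T cell list, whose median was -0.75 (score difference -0.80, SE 0.34). This cannot exclude it, because the antibody targets a T cell co-receptor and may itself have lowered that list. Isotype replicate 2 and DTA-1 replicate 2 had the highest T cell scores of their groups (1.07 and 0.23). DTA-1 replicate 3, with the highest B lineage score, had the lowest T cell score (-0.41). A smaller epithelial share alone would raise all other cell types alike, yet the B lineage score moved away from the T cell score by 3.07 (SE 0.87, log2). That contrast cannot decide either, because the T cell score in it may have changed with the antibody. The B lineage median shrank to 0.11 with the squamous score as covariate, so a part played by the epithelial share stays open. Dependence on 1 library is argued against by the lowest median of 1.63 over the 6 fits without single libraries. Fat or blood carried over with the tissue stays open, since the adipocyte or red cell scores were highest in isotype replicate 2 and DTA-1 replicates 2 and 3, although without DTA-1 replicate 3 the adipocyte median was -0.10 and the B lineage median 1.63. A link of the excess to GITR agonism was not tested and stays open, and isotype replicate 2, with Ighm at 187 CPM, shows that such levels also occurred without DTA-1.

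The brown fat gene Ucp1 stood at 74.2 CPM in isotype replicate 2 and 168 CPM in DTA-1 replicate 3, and at 6.70 CPM or less in the other 4 libraries. The osteopontin gene Spp1 stood at 178 CPM in isotype replicate 1 and at 1.23 to 3.25 CPM elsewhere. Besides Gkn1 and Atp4a, isotype replicate 3 carried the pepsinogen gene Pgc at 1180 CPM against 14.3 CPM or less in the other libraries, while the stomach gene Tff2 stood at 292 CPM in DTA-1 replicate 2, 25.2 CPM in isotype replicate 3 and 1.28 CPM or less elsewhere. The erythroid gene Alas2 stood at 107 CPM in DTA-1 replicate 2 against 2.27 to 4.65 CPM elsewhere.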
